A study of Homo sapiens with 34 samples.

How the data were processed

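The estimated counts used here were made by the authors with Cuffdiff, per the labels and the layout of the deposited tables, and 1 table of genes and 1 of isoforms was given for each kind of library. The submitters' processing notes name bcl2fastq for conversion of base calls, Trimmomatic for trimming, TopHat with Bowtie for alignment to GRCh37, and Cufflinks and Cuffdiff for estimation and scaling. The versions are not given in the sources used here. Long RNA was made into stranded libraries after removal of ribosomal RNA and read as pairs of 150 bases, and small RNA was read for 50 bases, on an Illumina HiSeq instrument. Per the labels, the cells came from the H9 line, hairpins were induced with doxycycline, and the germ layers were sorted after directed differentiation by a published protocol. The descriptions of the sorted layers all speak of endoderm precursors, while their titles and cell types differ, and the titles were used. A protocol note common to all samples also names hepatoblasts of another line, HUES64, so a difference in cell line between the layers and undifferentiated cells is not excluded.

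Each deposited column of estimated counts held 1 pooled value for the pair of libraries of a group, scaled by the authors to a common size, with a variance from their model and a status. The values were not rounded, transformed or scaled again. Estimates listed at 0 with a status of too many fragments, or in long RNA of a failed fit, were left out (34 to 52 long-RNA and 3 to 6 small-RNA features per comparison). In small RNA all 2 to 5 of a column had too many fragments, so that miRNAs such as MIR302A and MIR182 have no value in most columns. The isoform table of small RNA repeats the gene table and was not used here. Nor were 48 further columns that split each group's modelled variance into an uncertainty and a dispersion term. Of 52401 long-RNA identifiers 44056 had a symbol in the annotation (84.1%, with 96.8% of the counts), and of 1809 small-RNA identifiers 1530 did (84.6%, with 83.6%).

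The 23 comparisons (11 of long RNA, 12 of small RNA), the groups, the 51 gene lists and the rule for named genes were fixed before the data were examined. The plan was to test replicate libraries with edgeR. Since the columns were pooled, the thresholds planned for pooled values were used instead. The ratio was taken on a log2 scale after adding 1 count to each value. For U2AF1 knockdown the ratio is the mean of the log2 ratios of sets A and B, and the count is the mean of their counts. A feature was called at 2-fold with at least 200 counts in the higher group (50 in lists). Against a column at 0 a lower bound was computed with a floor of 3 counts over the group. Floors and modelled SDs cover counting error and the authors' model only, not differences between cultures. To see what the modelled variance alone gives, pairs of columns without a difference were drawn from it 20 times and counted alike.

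The named genes of a comparison were the target gene, then the 8 highest and 8 lowest ratios with a symbol (6 and 6 for small RNA), and up to 4 members of each list with the largest ratios. Some genes that this rule picked are not reported here. For isoforms the 5 genes with the largest moved share were named. SOX1, MIR127, MIR149 and MIR375 were followed across columns, and genes with recovered reads were picked for the text, after their values were seen.

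Of the 51 lists, 38 held genes of long RNA and 13 miRNAs. They covered pluripotency, the germ layers and their derivatives, signalling, stress and cell cycle responses, metabolism, RNA processing, imprinting and miRNA clusters. A list needed 3 measured members with at least 50 counts in the higher group. Its median was placed among 10000 random lists matched on mean expression in 20 bins, and lists outside the middle 95% were called.

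Reads per library were recovered as an alternative added later. The authors' scale factors of a pair of libraries restrict a pooled value under 100 to few pairs of whole read numbers, and a value was used when a single pair fitted. This gave reads for 75.3% of 108647 such long-RNA values and 94.2% of 2866 small-RNA values. The quasi-likelihood test of edgeR 4.0.16 was run on them with an adjusted p under 0.05, and again without each library in turn, where the lone library of a group was assumed to vary like the others. GC content was the second added alternative, in which the median ratio of each of 20 GC bins was subtracted. Isoforms were matched to the annotation by transcript identifier, which placed 118144 of 156600, with 82.5 to 85.1% of the counts, and a gene was used where its isoforms summed to its own count within 1%. The share moved is the summed gain of all isoforms that gained.

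Each step was tested on simulated data. In the NCBP1 comparison 98.1% of 105 genes changed 4-fold and 98.9% of 95 changed 8-fold passed 2-fold in the right direction, and 1149 of 12503 unchanged genes passed as well. With a GC trend added, 3441 unchanged genes passed before the correction and 1 after it. For the U2AF1 comparison 7% of random lists and 100% of shifted lists were called. Both libraries' reads were right for 100% of 14585 simulated scramble values. On other reads, drawn without recovery, edgeR called 5.97%, 68.7% and 98.5% of 67 genes each changed 2-, 4- and 8-fold and 3 of 4903 unchanged. For isoforms 100% of genes with 30% moved and 0% of unchanged genes passed, but read assignment was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.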

Results

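Per the labels, RNA was sequenced from H9, a human line described as induced pluripotent, and from transduced or differentiated cells. The series title names U2AF1, the small subunit of the factor that binds the 3' splice site, and asks about its part in self-renewal and differentiation of stem cells. The 34 libraries were made in 2 ways, 14 from long RNA after removal of ribosomal RNA and 20 from small RNA. Each group held 2 libraries, in 7 groups of long RNA and 10 of small RNA. Undifferentiated cells, cells after 10 days of a differentiation protocol, and cells with a doxycycline-induced short hairpin RNA were sequenced in both ways. The hairpins were a scramble control, 1 against NCBP1, 1 against EIF4A3, and a pair of sets named A and B against U2AF1, and the labels do not say how A differs from B. NCBP1 is the large subunit of the nuclear cap binding complex, and EIF4A3 is the helicase that anchors the exon junction complex. Small RNA was also sequenced from sorted cells of the ectoderm, mesoderm and endoderm, perhaps of another line.

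The values were the authors' estimated fragment counts, scaled by the authors and given as a single pooled value per group and feature. There were therefore no replicate values, and no test was made on the pooled values. A gene was called higher or lower at a 2-fold difference with at least 200 counts in the higher group (50 within lists). Column totals (M, 1e6 counts) were 62.6 M counts in undifferentiated cells, 54.7 M at day 10, 59.5 M with scramble, 59.8 M with U2AF1 A, 60.9 M with U2AF1 B, 57.9 M with the NCBP1 hairpin and 57.2 M with the EIF4A3 hairpin. Small-RNA totals ran from 3.05 to 6.77 M. Between 12222 and 12989 long-RNA features, and between 198 and 228 small-RNA features, reached 200 counts in a column. The authors' model gave a median coefficient of variation of 16.9 to 17.2% for long RNA and 26.1 to 27.1% for small RNA. Values for U2AF1 knockdown without a letter are means of A and B, and log2 ratios were computed after adding 1 count. Positions are on build GRCh37.

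Among the transduced columns each target transcript had its lowest value in its own knockdown, and only U2AF1, in set B and in the mean of both sets, passed 2-fold. U2AF1 (ENSG00000160201, chr21:44513066-44527680) was at 8182 counts with scramble (modelled SD 1288), 5661 with set A (912) and 2818 with set B (463), so the mean of both was 4240 and its log2 ratio -1.03. NCBP1 (ENSG00000136937, chr9:100395950-100436030) was at 9868 counts with scramble (modelled SD 1823) and 5675 with its hairpin (1095), a log2 ratio of -0.80. EIF4A3 (ENSG00000141543, chr17:78108168-78120950) was at 6760 counts with scramble (modelled SD 1062) and 4523 with its hairpin (743), a log2 ratio of -0.58. The U2AF1 transcript stood at 5788 counts in the NCBP1 column and 6457 in the EIF4A3 column. Undifferentiated cells held 8657 counts of U2AF1, 10451 of NCBP1 and 5878 of EIF4A3. At day 10 the 3 transcripts stood at 7115, 5795 and 2689 counts.

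**Figure D1:**
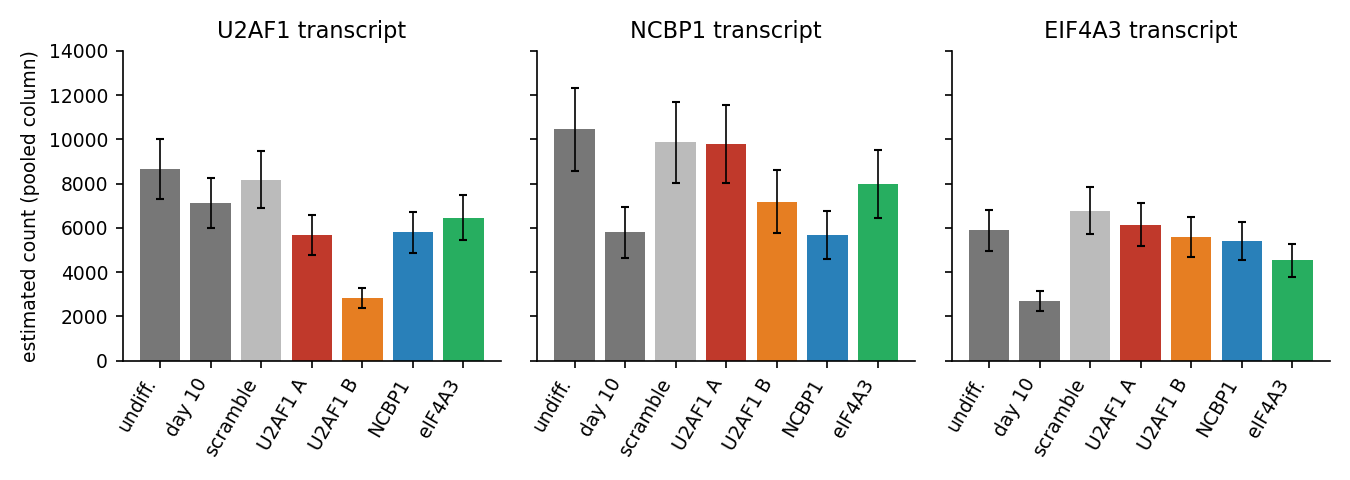
Estimated counts (pooled value of 2 libraries) of the U2AF1, NCBP1 and EIF4A3 transcripts in each of the 7 long-RNA columns, with bars showing the authors' modelled SD on either side. Each target was lowest among the transduced columns in its own knockdown, at 2818 counts for U2AF1 with set B, 5675 for NCBP1 and 4523 for EIF4A3.

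Comparing day 10 with undifferentiated cells asked what the differentiation protocol had done. At day 10 the cells held transcripts of neural crest, surface ectoderm, amnion and connective tissue that undifferentiated cells nearly lacked, and less of the pluripotency and sterol synthesis transcripts. The nuclear receptors NR2F1 (1870.1 against a listed 0, at least 623-fold) and NR2F2 (5821 against 3.94, log2 10.20), the transcription factors TFAP2B (3651 against 1.07, log2 10.78) and PAX3 (6434 against 9.43, log2 9.27), the collagen COL3A1 (7847 against 4.71, log2 10.42) and the integrin ITGB6 (2028 against 0.998, log2 9.99) stood highest by ratio. MUC15 (3722 against 2.72, log2 9.97) and the neurotrophin receptor NTRK2 (3642 against 4.22, log2 9.45) completed the 8 highest. The 8 lowest were TMEM26 (1.37 against 339, log2 -7.16), D21S2088E (13.1 against 1847), the cytochrome CYP2B6 (9.74 against 981), the eye-field factor SIX6 (12.5 against 771), VWC2 (6.49 against 420.3), LINC01487 (8.28 against 438), VN1R51P (4.48 against 224) and FOXL2NB (24.8 against 946).

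Of 13483 features with at least 200 counts, 3462 passed 2-fold at day 10, 2010 higher and 1452 lower. Columns drawn at random from the authors' modelled variance gave 1355 such features on average, and 2831 of the 3462 differed by more than 2 modelled SDs. With columns scaled to equal totals, which moved the median log2 ratio by 0.20, 2576 were higher and 961 lower. The ratios rose with transcript GC content (Spearman 0.303 across genes), and GC correction left 1614 higher and 1237 lower.

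The pluripotency core list had 1 higher and 16 lower of 27, median log2 -1.04, led by the Nodal antagonist LEFTY1 (73.3 against 1727) with GDF3 (186 against 3579) and NODAL (909.7 against 6502). Among naive pluripotency genes (6 higher and 2 lower of 8, median log2 1.59), TBX3 (763 against 77.2) and KLF5 (907 against 101) were higher and TFCP2L1 (155 against 552) was lower. The neural crest list (13 higher and 0 lower of 14, median log2 6.37) included MSX2 (3342 against 7.16), and its median was 5.57 with 1 member at 0 set to its bound. In the surface ectoderm list (10 higher and 0 lower of 12, median log2 3.91) TFAP2A (7849.8 against 22.2) and the epidermal factor TP63 (2116 against 6.71) stood out. The trophoblast and amnion list (14 higher and 0 lower of 17, median log2 5.17) shares TFAP2A and TP63 with it and adds ELF5 (550.3 against 1.72). The ectoderm and neural list had 9 higher and 2 lower of 17, median log2 1.52, with LMX1A (848 against 0.499) and NEUROD1 (203 against 2.99) among the higher. Mesoderm genes (12 higher and 5 lower of 20, median log2 1.86) included the heart genes MYH6 (189 against a listed 0) and ISL1 (499 against 8.30). Endoderm genes (8 higher and 1 lower of 11, median log2 2.46) included GATA6 (89.2 against a listed 0). The HOX list had 3 higher and 0 lower of 3, median log2 3.03.

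The extracellular matrix list had 13 higher and 1 lower of 19, median log2 2.47, with LUM (951 against 1.57) and COL1A1 (8147 against 224). In the list for epithelial to mesenchymal transition (8 higher and 1 lower of 15, median log2 2.12) ZEB2 (7291 against 23.5) and VIM (29966 against 869) were higher. The WNT list had 9 higher and 3 lower of 17, median log2 1.03. The Nodal, TGF-beta and BMP list had 9 higher and 7 lower of 19, median log2 0.96 (0.45 after correction for GC content), with the BMP antagonist NOG (578 against 6.73). Imprinted genes (6 higher and 0 lower of 14, median log2 0.81) included IGF2 (5001 against 32.05) and PEG3 (3395 against 22.5). Immediate early genes (8 higher and 2 lower of 17, median log2 0.95) included EGR1 (959 against 22.4). The p53 target list (10 higher and 2 lower of 25, median log2 0.69) held BTG2 (2016 against 111) and CDKN1A (1725 against 234), while PMAIP1 (1107 against 6932) was lower. Glycolysis and hypoxia genes (8 higher and 0 lower of 22, median log2 0.88) were led by NDRG1 (1978 against 86.8).

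Nearly every sterol synthesis gene was lower at day 10, with 0 higher and 19 lower of 20, median log2 -1.71, for instance HMGCS1 (7814 against 50761). The G1/S list (0 higher and 9 lower of 19, median log2 -0.99) held RRM2 (4127 against 17576). The unfolded protein response list (0 higher and 6 lower of 12, median log2 -1.01) was led by HSPA5 (15428 against 45422). Mitochondrial genome transcripts had 0 higher and 5 lower of 12, median log2 -0.93, nuclear oxidative phosphorylation genes had 0 higher and 4 lower of 26, median log2 -0.60, and snoRNA host genes had 0 higher and 5 lower of 12, median log2 -0.89. Ribosomal protein genes had 2 higher and 0 lower of 35, median log2 0.31. Each list named so far had a median outside the middle 95% of 10000 random lists matched on expression.

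The medians of 14 more lists lay inside that range at day 10. In those for RNA processing, the U2 auxiliary factor and U2 snRNP list had 1 higher and 2 lower of 21, median log2 -0.28, SR proteins and hnRNPs 0 higher and 1 lower of 25, median log2 -0.63, the cap binding complex and export 0 higher and 0 lower of 14, median log2 -0.25, and the exon junction complex 0 higher and 1 lower of 11, median log2 -0.39. Nonsense-mediated decay factors had 0 higher and 0 lower of 14, median log2 -0.12, their targets 5 higher and 4 lower of 34, median log2 -0.20, and the miRNA machinery 1 higher and 1 lower of 16, median log2 -0.09. Endothelium and blood genes had 2 higher and 1 lower of 9, median log2 0.20, interferon response genes 4 higher and 2 lower of 11, median log2 0.38, and heat shock proteins 2 higher and 4 lower of 10, median log2 -0.23. The integrated stress response list had 3 higher and 5 lower of 18, median log2 -0.16. G2/M genes had 0 higher and 4 lower of 20, median log2 -0.56, replication-dependent histones 1 higher and 1 lower of 17, median log2 -0.14, and apoptosis regulators 2 higher and 4 lower of 17, median log2 -0.23. After correction for GC content the G2/M (-0.54) and apoptosis (-0.46) medians lay outside it, and no list called at day 10 moved inside.

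**Figure D2:**
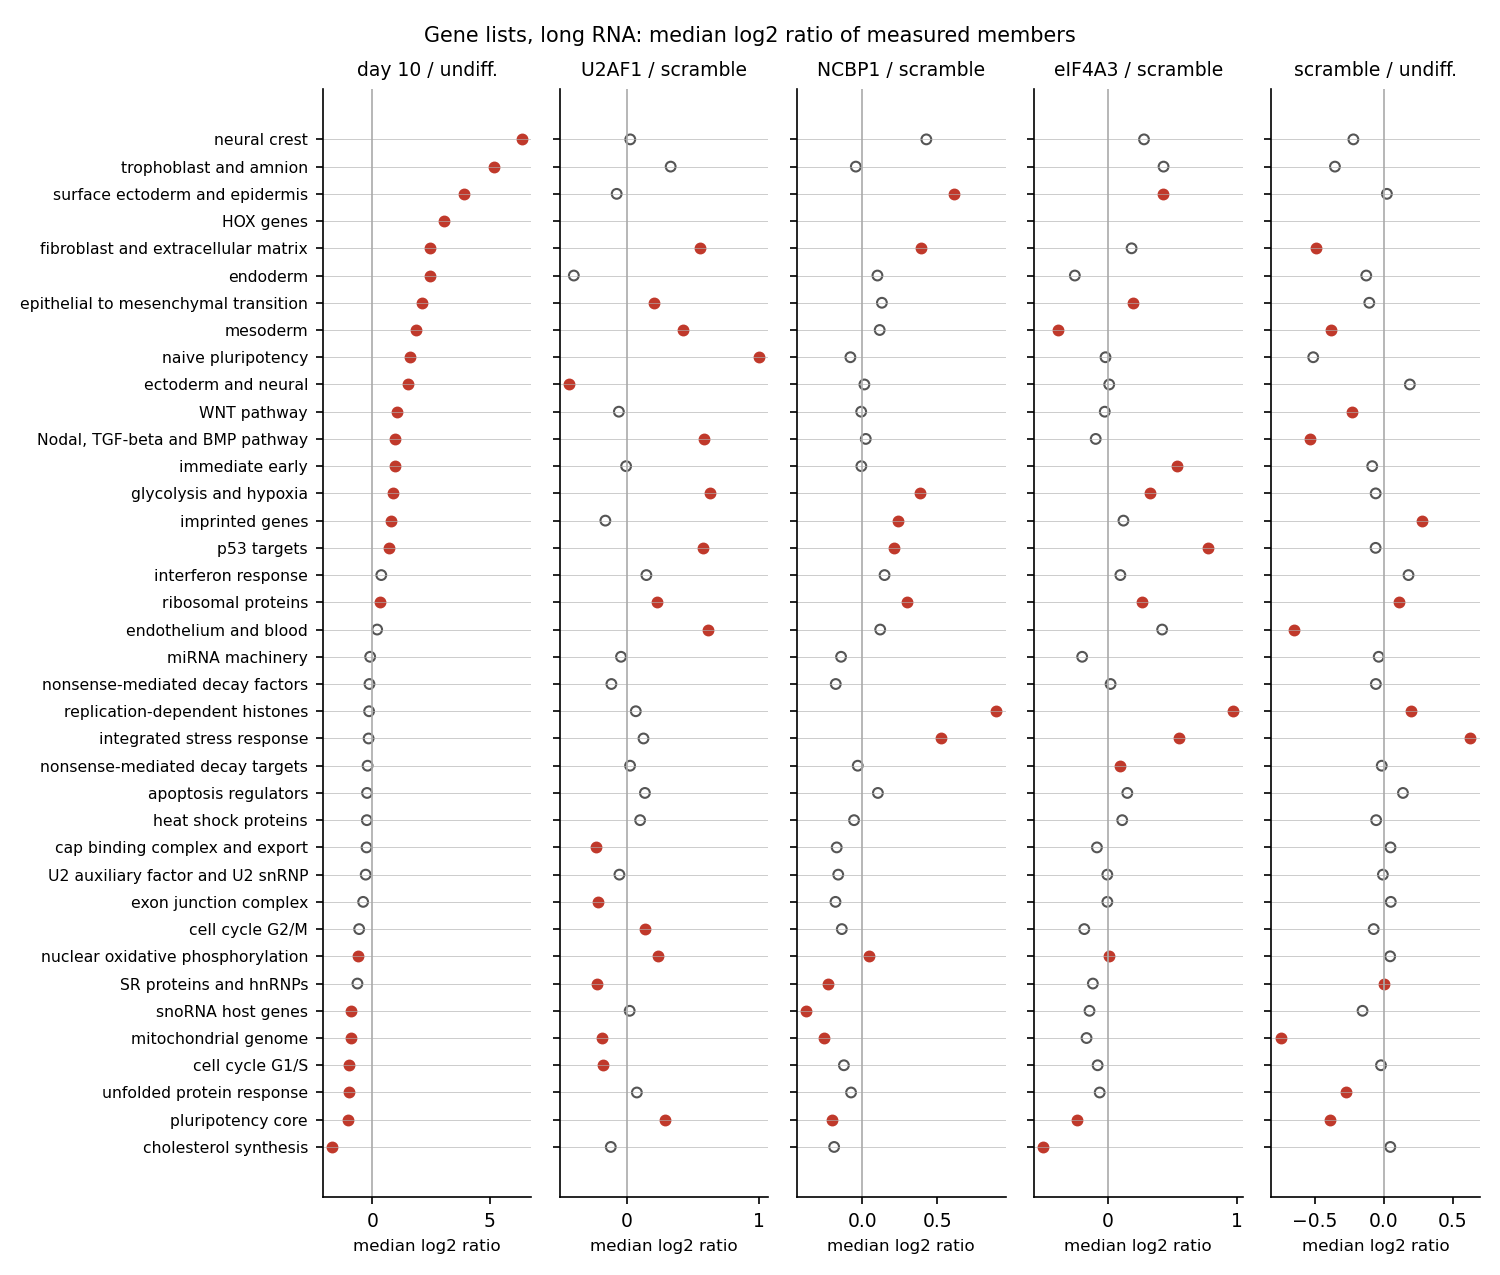
Median log2 ratio of the measured members of each long-RNA gene list (horizontal axis, no unit) in 5 comparisons, where filled red points lie outside the middle 95% of matched random lists and open points inside. The neural crest list reached 6.37 at day 10, while the histone list reached 0.89 with the NCBP1 hairpin and 0.97 with the EIF4A3 hairpin.

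U2AF1 knockdown was compared with scramble to ask what differed with hairpins against the splicing factor. With both U2AF1 sets the X-linked BEX5 (347 against a listed 0, at least 116-fold), complement C3 (911 against 20.7, log2 5.34), the otoconial protein gene OC90 (838 against 27.3, log2 4.86), SPOCK3 (1316 against 39.5, log2 4.76) and the Nodal antagonist CER1 (567 against 42.5, log2 3.67) were higher than with scramble. Higher too were LINC01108 (1264 against 55.5, log2 4.25), the chemokine receptor CCR4 (232 against 10.9) and MYCT1 (217 against 6.50). The limb and neural factors TBX15 (37.3 against 1128, log2 -5.02) and SOX1 (65.7 against 1568, log2 -4.58), the muscle and crest factor PAX7 (314 against 2464, log2 -3.10), MSANTD3-TMEFF1 (223 against 2413, log2 -3.53), LINC01139 (40.5 against 330.1), COL8A1 (125 against 840.3) and SLFN13 (741 against 5511) were lower. Mitochondrial 12S RNA, MT-RNR1 (18485 against 252385, log2 -3.77), was among the 8 lowest, though it and MSANTD3-TMEFF1 differed by only 1.61 and 0.885 modelled SDs.

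Of 12628 features, 561 passed 2-fold, 316 higher and 245 lower, of which 460 differed by more than 2 modelled SDs. Draws from the modelled variance gave 940.4 on average. In every long-RNA comparison except day 10 and U2AF1 against NCBP1 knockdown, such draws gave more features past 2-fold than were observed, so a single gene near the threshold was not told from that variance. Of the 561 genes, 35.8% stayed past 2-fold in the same direction against undifferentiated cells (122 higher and 79 lower), and 70.8% did so against the mean of the NCBP1 and EIF4A3 columns (216 and 181). SOX1 was at 63.3 counts in undifferentiated cells, 1568 with scramble, 78.8 with set A and 52.7 with set B.

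Among the lists, the pluripotency core had 3 higher and 0 lower of 27, median log2 0.29, with GDF3 (3244 against 1434). Naive pluripotency genes (4 higher and 0 lower of 7, median log2 1.003) included DPPA5 (90.2 against 6.50). The p53 target list (8 higher and 0 lower of 25, median log2 0.58) held GDF15 (163 against 12.2), the cell cycle inhibitor CDKN1A (1153 against 148) and BTG2 (499 against 64.9). Glycolysis and hypoxia genes (7 higher and 0 lower of 22, median log2 0.63) included BNIP3 (8643 against 2004). The Nodal, TGF-beta and BMP list had 4 higher and 0 lower of 18, median log2 0.58, with BMP4 (424 against 119) and BAMBI (2541 against 1220.5). Extracellular matrix genes (2 higher and 0 lower of 15, median log2 0.55) included COL6A3 (487 against 209.95). In the mesoderm list (4 higher and 2 lower of 13, median log2 0.42) BMP4 and the VEGF receptor KDR (10729 against 3459) were higher, and TBX5 (1.21 against 78.8) was lower. The endothelium and blood list (2 higher and 2 lower of 7, median log2 0.62) ranged from the globin HBE1 (166 against 2.15) to TAL1 (14.4 against 155). The list for epithelial to mesenchymal transition (0 higher and 2 lower of 13, median log2 0.21) had ZEB1 (51.1 against 257) and ZEB2 (44.3 against 251) among the lower. Neural genes (1 higher and 3 lower of 12, median log2 -0.44) included MAP2 (1599 against 8886), which was lower, and PAX6 (858 against 206), which was higher. The pluripotency core, Nodal, matrix, mesoderm and endothelium medians had the opposite sign with scramble against undifferentiated cells (-0.39, -0.53, -0.49, -0.38 and -0.65).

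RNA processing lists moved little in U2AF1 knockdown. SR proteins and hnRNPs had 0 higher and 0 lower of 25, median log2 -0.23, the cap binding complex and export 0 higher and 0 lower of 14, median log2 -0.23, and the exon junction complex 0 higher and 0 lower of 11, median log2 -0.22. Ribosomal proteins had 0 higher and 0 lower of 35, median log2 0.23, nuclear oxidative phosphorylation genes 0 higher and 0 lower of 26, median log2 0.24, G1/S genes 0 higher and 0 lower of 19, median log2 -0.19, G2/M genes 0 higher and 0 lower of 20, median log2 0.14, and mitochondrial transcripts 0 higher and 2 lower of 15, median log2 -0.19. These lists too lay outside the middle 95% of matched random lists, but after correction for GC content those for the exon junction complex (-0.16), G2/M (0.16) and epithelial to mesenchymal transition (0.18) lay inside it. Nonsense-mediated decay targets (2 higher and 1 lower of 34, median log2 0.02) and the U2 list (0 higher and 1 lower of 21, median log2 -0.06) did not.

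Reads per library were recovered for features with values under 100 counts, and edgeR called 360 of 5068 features in U2AF1 knockdown, 202 higher and 158 lower, of which 59 were called whichever library was left out. TBX5 had 1, 1, 2 and 1 reads in the knockdown libraries and 115 and 64 with scramble (adjusted p 8.74e-12). FOXA1, a pioneer factor of endoderm, had 4, 4, 1 and 2 against 96 and 85 reads (adjusted p 3.03e-11). The endoderm factor SOX17 had 10, 16, 32 and 29 reads against 0 and 0 (adjusted p 2.2e-05). With 1 library left out the highest adjusted p of these 3 genes were 2.57e-06, 2.53e-06 and 0.00871. The labels do not say whether the 2 libraries of a group came from separate cultures, so the spread between them was not read as biological.

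Many genes were called in the same direction with both U2AF1 sets. Against scramble, 623 genes passed 2-fold with set A (394 higher, 229 lower) and 848 with set B (433 higher, 415 lower, but 378 and 482 with equal totals and 528 and 347 with median-ratio scaling). Among 12466 features measured in both, 189 were higher and 147 lower with both sets and 0 went in opposite directions. A common control alone makes some genes shared, and no usable chance count was had, since draws from the modelled variance passed more features (1166 and 1122) than were observed. The log2 ratios correlated across genes, which are not independent replicates (r 0.664, covariance 0.190), where such draws with a common scramble gave 0.492 and 0.346. Only with set A did the deiodinase gene DIO3 (229 against 4.50) and ANXA1 (597 against 30.2) rank among the 8 highest, and only with set B did VAV1 (212 against a listed 0, at least 70.5-fold) and MAGEA4 (227 against 12.05). DOK1 (53.7 against 373) and LRP1B (119 against 772) were among the lowest with set A, and ZEB2 (19.4 against 251) and PRKDC (25.9 against 1704) with set B, but DOK1 with A and PRKDC with B differed by only 1.14 and 0.428 modelled SDs.

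Set A was also compared with set B, to ask if they differed. The muscle genes TAGLN (1805 against 7108, log2 -1.98), MYL9 (295 against 1412, log2 -2.26) and ACTC1 (126 against 461, log2 -1.86) were lower with A than with B, as were FZD2 (68.9 against 248) and PMPCAP1 (65.5 against 319.6), while MYCT1 (408 against 25.7, log2 3.94) and DIO3 (229 against 27.1) were higher. In all, 512 of 12605 features passed 2-fold, 239 higher and 273 lower with A. Ratios fell with transcript GC content across genes (Spearman -0.567, against -0.267 for A and 0.304 for B compared with scramble), and subtracting the median of each GC bin left 183 higher and 56 lower. Median-ratio scaling gave 187 higher and 413 lower, and equal totals 262 and 232. Ribosomal proteins had 0 higher and 2 lower of 35, median log2 -0.49, and replication-dependent histones 0 higher and 3 lower of 17, median log2 -0.62 (-0.38 after GC correction). On recovered reads edgeR called 84 features higher and 5 lower with A, 6 of them whichever library was left out.

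NCBP1 knockdown was compared with scramble to ask what differed with a hairpin against the cap binding protein. Replication-dependent histone genes were higher as a group (7 higher and 1 lower of 17, median log2 0.89), with H3C13 (409 against 67.2, log2 2.59), H2AC7 (835 against 155, log2 2.42) and H4C11 (7281 against 1849, log2 1.98), whereas the linker histone gene H1-1 (42.2 against 1453, log2 -5.07) had the lowest ratio of the genes named. Zinc finger gene ZNF676 (662 against 5762, log2 -3.12), FEZF1-AS1 (91.1 against 297), the caveolae gene CAV1 (192 against 584), PKIA-AS1 (72.9 against 201), RSC1A1 (237 against 622), SLC2A3P1 (133 against 350.004) and MT-RNR1 (38841 against 252385, log2 -2.70) were lower, but H2AC7, PKIA-AS1, RSC1A1, SLC2A3P1 and MT-RNR1 differed by only 0.951, 0.828, 0.637, 0.306 and 1.47 modelled SDs. Higher were the platelet and endothelial gene MMRN1 (264 against 52.9), MCRIP2 (232 against 53.4), the metalloprotease MMP17 (618 against 151), the complex I gene NDUFB7 (1354 against 345) and FNDC10 (527 against 138).

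Of 12650 features, 419 passed 2-fold, 376 of them higher and 43 lower, with 318 beyond 2 modelled SDs. The ratios rose with transcript GC content (Spearman 0.663 across genes), and the higher genes had a median GC content of 63.6% against 47.2% for all. After the median of each GC bin was subtracted, 54 were higher and 24 lower. Columns drawn from the modelled variance gave 1122 on average.

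Each list below is given with its median before and after that GC correction, since GC content moved with the knockdown. The histone median was 0.89 and became 0.66. Integrated stress response genes had 3 higher and 0 lower of 18, median log2 0.52 (0.51 after correction), with DDIT4 (3895 against 1323). The p53 target list had 5 higher and 0 lower of 24, median log2 0.21 (0.21), with PHLDA3 (172 against 66.1). Glycolysis and hypoxia genes had 1 higher and 0 lower of 22, median log2 0.39 (0.26), and ribosomal proteins 1 higher and 0 lower of 35, median log2 0.30 (0.28). The snoRNA host genes had 0 higher and 0 lower of 12, median log2 -0.37 (-0.31). The pluripotency core had 0 higher and 1 lower of 27, median log2 -0.20 (-0.23). Extracellular matrix genes had 2 higher and 0 lower of 15, median log2 0.39 (0.22). Surface ectoderm genes had 0 higher and 0 lower of 5, median log2 0.61 (0.11), and imprinted genes 0 higher and 0 lower of 11, median log2 0.24 (0.05), and after correction both lay inside the middle 95%. Mesoderm genes (2 higher and 1 lower of 14, median log2 0.12) lay inside it before correction and at a median of -0.33 outside it after.

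SR proteins and hnRNPs had 0 higher and 0 lower of 25, median log2 -0.22 and mitochondrial transcripts 0 higher and 1 lower of 15, median log2 -0.25, both outside the middle 95%, and after GC correction the first (-0.05) lay inside it and the second (-0.15) outside. The cap binding list itself had 0 higher and 0 lower of 14, median log2 -0.17, inside it. With recovered reads edgeR called 34 of 5066 features, 23 higher and 11 lower, and 1 of them whichever library was left out.

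The EIF4A3 hairpin was compared with scramble to ask what differed with a hairpin against the exon junction helicase. The stress hormone gene GDF15 (213 against 12.2, log2 4.02), the smooth muscle actin ACTA2 (269 against 23.3, log2 3.47), PPP1R16A (833 against 93.05, log2 3.15), the p53 targets BTG2 (471 against 64.9, log2 2.84) and PHLDA3 (327 against 66.1, log2 2.29), the toll-like receptor TLR4 (253 against 35.8), H3C13 (448 against 67.2) and MMRN1 (334 against 52.9) were highest against scramble. LINC01139 (32.5 against 330.1, log2 -3.31), MT-RNR1 (31669.8 against 252385, log2 -2.99), ZNF252P (517 against 1823), the germline gene DPPA3 (64.6 against 222), SLC2A3P1 (117 against 350.004), ARNT (2668 against 7324) and EBF2 (438 against 1127) were among the lowest. GDF15, MT-RNR1 and SLC2A3P1 differed by only 0.744, 1.52 and 0.338 modelled SDs.

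Of 12615 features, 334 passed 2-fold, 292 higher and 42 lower, with 256 beyond 2 modelled SDs. Here also the ratios rose with GC content (Spearman 0.641 across genes, median GC content of the higher genes 62.9%), and GC correction left 82 higher and 27 lower. Draws from the modelled variance gave 1115 on average. The p53 target list had 8 higher and 0 lower of 25, median log2 0.77 (0.77 after GC correction), with CDKN1A (518 against 148) besides those named. Integrated stress response genes had 5 higher and 0 lower of 18, median log2 0.55 (0.46), with CHAC1 (2053 against 622). Histones had 5 higher and 0 lower of 17, median log2 0.97 (0.77). Immediate early genes had 4 higher and 0 lower of 16, median log2 0.53 (0.45), with FOSB (57.4 against 1.38). Cholesterol synthesis had 0 higher and 0 lower of 20, median log2 -0.50 (-0.47). Nonsense-mediated decay targets had 4 higher and 0 lower of 34, median log2 0.10 (0.13). The pluripotency core had 0 higher and 2 lower of 27, median log2 -0.24 (-0.24).

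Mesoderm genes had 2 higher and 0 lower of 13, median log2 -0.38 (-0.50 after GC correction), with TAGLN (5769 against 1594) higher, while PDGFRA (267 against 472) did not pass 2-fold. The list for epithelial to mesenchymal transition had 3 higher and 0 lower of 14, median log2 0.20, with ZEB1 (655 against 257), and its median became -0.02 after GC correction. Surface ectoderm genes had 0 higher and 0 lower of 5, median log2 0.43 (0.13 after GC correction, inside the middle 95%). Glycolysis and hypoxia genes had 1 higher and 0 lower of 22, median log2 0.32 and ribosomal proteins 1 higher and 0 lower of 35, median log2 0.26, and nuclear oxidative phosphorylation genes 0 higher and 0 lower of 26, median log2 0.01 (0.14 after correction). Each list median given here for this knockdown lay outside the middle 95% before correction. From recovered reads edgeR called 23 of 5278 features, 17 higher and 6 lower, and 3 of them whichever library was left out.

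**Figure D3:**
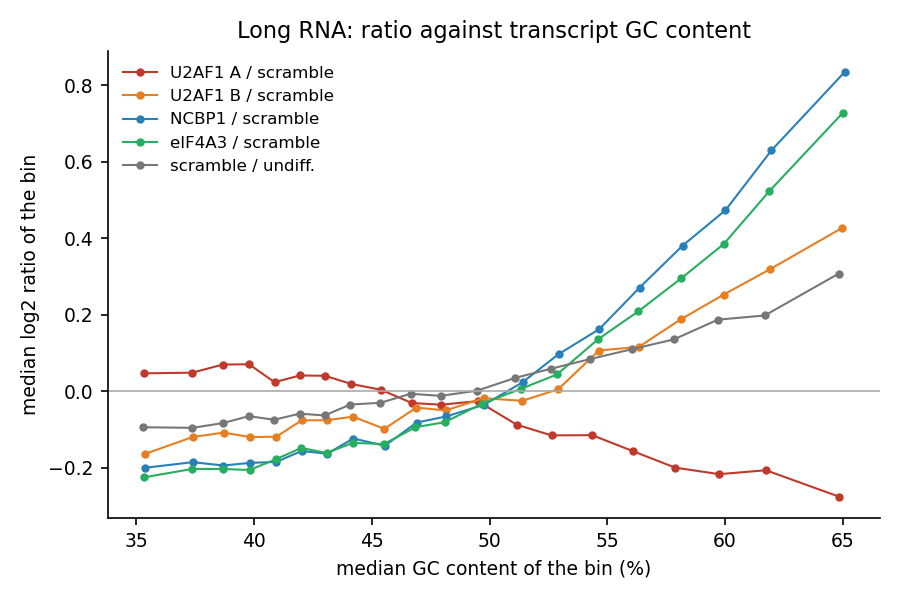
Median log2 ratio (vertical axis) of 20 bins of genes against the median GC content of each bin in percent (horizontal axis), for 5 comparisons of pooled long-RNA columns, where each point is 1 bin. The lines for NCBP1 and EIF4A3 knockdown climbed with GC content (Spearman 0.663 and 0.641 across genes), that for U2AF1 A fell (-0.267), and those for U2AF1 B and scramble against undifferentiated climbed less (0.304 and 0.322).

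The knockdowns were compared with one another to ask whether they gave the same response. NCBP1 and EIF4A3 knockdown shared 215 higher and 17 lower genes, with 0 in opposite directions and r 0.865 across genes (covariance 0.148). Here too no chance count was usable, and draws with a common scramble gave r 0.491 and covariance 0.338. After GC correction 39 and 8 were shared (r 0.723). Compared directly, only 32 of 12584 features passed 2-fold, 10 higher and 22 lower with the NCBP1 hairpin. H1-1 (42.2 against 2842, log2 -6.04), ZNF676 (662 against 5388, log2 -3.02), GDF15 (25.5 against 213, log2 -3.02), EGR1 (53.5 against 238), PPP1R16A (192 against 833), GREM1 (73.3 against 250.3), ACTA2 (83.5 against 269) and BTG2 (151 against 471) were lower with the NCBP1 hairpin. LINC01139 (293 against 32.5, log2 3.14), SNORA63 (2262 against 756), IGIP (266 against 109), FOXL2NB (1183 against 500.3), MIR4458HG (416 against 185), ZNF252P (1088 against 517), CDRT4 (299 against 144) and ASIC2 (339 against 168) were higher. GDF15, SNORA63, CDRT4, ACTA2 and ASIC2 differed by 0.667, 0.492, 0.550, 1.71 and 1.89 modelled SDs. On recovered reads edgeR called 25 features, 3 of them whichever library was left out.

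U2AF1 knockdown shared 9 higher and 6 lower genes with NCBP1 knockdown (8 opposite, r 0.207), or 4 and 2 after GC correction. With EIF4A3 knockdown it shared 19 and 7 (13 opposite, r 0.184), or 11 and 2. Common-scramble draws (r 0.575 and 0.592) spread too much to test a shared response. Against NCBP1 knockdown 950 of 12770 features passed 2-fold in U2AF1 knockdown, 340 higher and 610 lower. Against EIF4A3 knockdown 908 of 12735 did, 405 and 503. These ratios fell with GC content (Spearman -0.514 and -0.464 across genes), and GC correction left 335 and 277, and 380 and 274.

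Several genes stood among the highest or lowest in both of these comparisons. Against NCBP1 knockdown, BEX5 (347 against 2.65), MYCT1 (217 against 0.435), OC90 (838 against 10.6), H1-1 (2813 against 42.2), C3 (911 against 13.98), LINC01108 (1264 against 18.4), SPOCK3 (1316 against 24.7) and CCR4 (232 against 8.83) were higher, and TBX15 (37.3 against 1113), SOX1 (65.7 against 1845), MMRN1 (14.9 against 264), PRKDC (1479 against 4059, a mean of 2933 in A and 25.9 in B), MSANTD3-TMEFF1 (223 against 2415), PAX7 (314 against 3312), HMX2 (21.4 against 220.1) and ZEB1 (51.1 against 459) lower. Against EIF4A3 knockdown, OC90, LINC01108, C3, SPOCK3, BEX5 and MYCT1 were again among the highest, with HHLA1 (5213 against 260.1) and PAICSP7 (213 against 11.5). TLR4 (8.70 against 253), GREM1 (13.6 against 250.3), CDH10 (15.3 against 258), ZEB2 (44.3 against 605) and TAL1 (14.4 against 218) joined MMRN1, SOX1 and TBX15 among the lowest. With recovered reads edgeR called 571 features against NCBP1 knockdown and 564 against EIF4A3 knockdown, 139 and 150 of them whichever library was left out.

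The response to each hairpin was also set beside the change at day 10, with which it shares no library. Day 10 and U2AF1 knockdown shared 94 higher and 44 lower genes (27.8 and 24.7 expected if independent), while 118 went in opposite directions (52.9 expected, r 0.0793 across genes). Day 10 and NCBP1 knockdown shared 186 and 16 (expected 34.0 and 4.55, 5 opposite against 39.7, r 0.439), and day 10 and EIF4A3 knockdown 138 and 18 (expected 26.4 and 4.11, 5 opposite against 31.5, r 0.438). After GC correction the shared genes were 95 and 32, 19 and 13, and 40 and 14.

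Scramble was compared with undifferentiated cells to ask what transduction, the hairpin vector and doxycycline had done without a target. Several genes were on in one and nearly off in the other. The zinc finger gene ZNF729 (15.2 against 27186, log2 -10.72), JRK (1.87 against 688, log2 -7.91), the endothelin receptor EDNRB (2.35 against 623, log2 -7.54), PAX8-AS1 (6.16 against 1153), PAX8 (7.27 against 309), ZNF558 (0.968 against 265), RGPD2 (2.98 against 285) and LINC01487 (74.5 against 438) were lower with scramble. ZNF736 (1949 against 6.36, log2 8.05), AACSP1 (482 against 0.573), TRIM4 (485 against 2.64, log2 7.06), the protease CTSF (959.8 against 11.4, log2 6.27), CCDC144NL-AS1 (565 against 16.2), SOX1 (1568 against 63.3, log2 4.61), LINC02693 (806 against 36.5) and MSANTD3-TMEFF1 (2413 against 197) were higher. In all, 303 of 12588 features passed 2-fold, 129 higher and 174 lower (174 and 132 with equal totals), and 225 differed by more than 2 modelled SDs. Columns drawn from the modelled variance gave 1164 on average, and MSANTD3-TMEFF1 differed by 1.12 modelled SDs.

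The pluripotency core (0 higher and 3 lower of 27, median log2 -0.39) was lower with scramble, as was the Nodal, TGF-beta and BMP list (0 higher and 5 lower of 18, median log2 -0.53). Integrated stress response genes (3 higher and 0 lower of 18, median log2 0.63) were higher. Mitochondrial transcripts had 0 higher and 0 lower of 12, median log2 -0.75, extracellular matrix genes 0 higher and 1 lower of 16, median log2 -0.49, mesoderm genes 0 higher and 2 lower of 13, median log2 -0.38, and endothelium and blood genes 0 higher and 3 lower of 8, median log2 -0.65. Imprinted genes had 1 higher and 1 lower of 11, median log2 0.27, with H19 (163 against 1.72). These 8 medians lay outside the middle 95% of matched random lists. From recovered reads edgeR called 70 features, 25 higher and 45 lower, and 2 of them whichever library was left out.

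**Figure D4:**
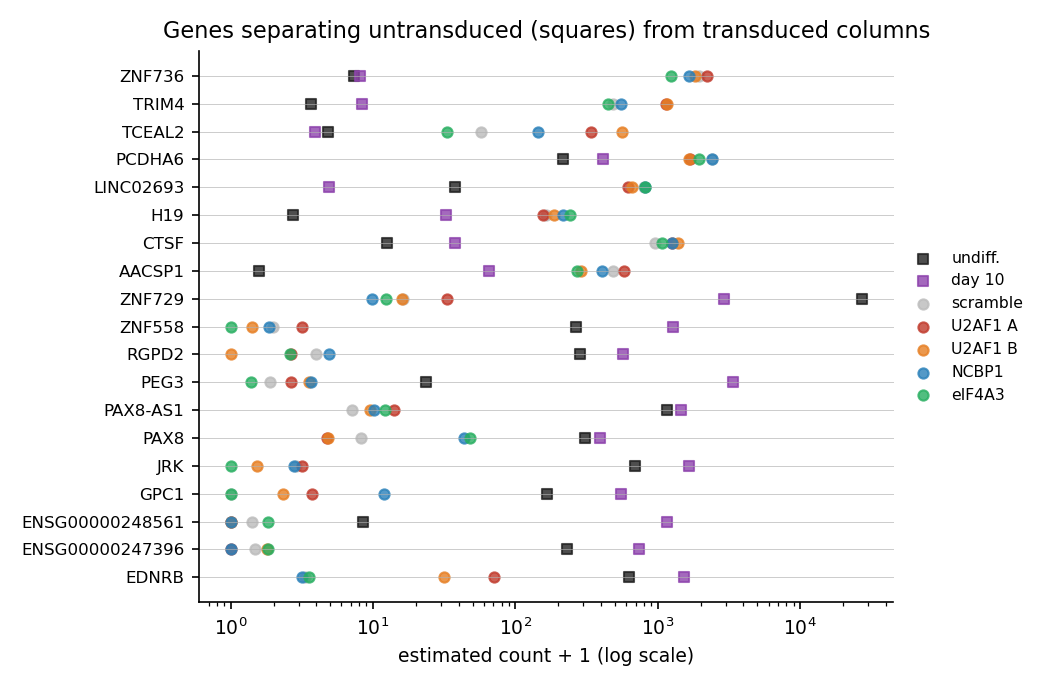
Estimated count plus 1 (horizontal log axis) of the 19 genes that separated the 2 untransduced columns (squares) from the 5 transduced columns (circles) by at least 4-fold, where each point is 1 pooled column. ZNF729 stood at 27186 and 2915 counts in the untransduced columns and at 8.80 to 31.97 in the transduced ones, and ZNF736 at 6.36 and 7.04 against 1232 to 2232.

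Isoform shares were compared to ask where splicing or transcript choice differed. A gene was called when at least 20% of its counts moved between isoforms, with at least 500 in both groups. No chance count was made. In U2AF1 knockdown 80 of 3909 genes passed, in NCBP1 knockdown 158 of 4110, in EIF4A3 knockdown 125 of 4080, with scramble against undifferentiated 84 of 4076, and at day 10 297 of 3837. Set A gave 107 of 4061 genes against scramble, set B 190 of 4069, and A against B 160 of 4078. U2AF1 knockdown gave 108 of 3877 against NCBP1 and 113 of 3856 against EIF4A3 knockdown, which differed from each other in 25 of 4220. SGMS1 had 58.7% of its counts on SGMS1-201 in U2AF1 knockdown and 0.195% with scramble, but 50.0% in undifferentiated cells. For ITGA5, the coding isoform ITGA5-201 held 75.3% in U2AF1 knockdown and 33.7% with scramble, and ITGA5-202, annotated as subject to nonsense-mediated decay, 24.7% and 66.3%. USP30-201 held 69.5% against 30.6%, RPL39L-202 77.1% against 29.7%, and ATOSA-202 59.5% against 20.7%. In undifferentiated cells ITGA5-201, USP30-201, RPL39L-202 and ATOSA-202 held 36.0%, 64.0%, 81.6% and 41.3%.

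In NCBP1 knockdown ASB6-201 held 80.1% against 20.9% with scramble, MINK1-202 63.5% against 8.89%, GAS7-204 22.3% against 75.6%, MRC2-201 56.3% against 7.89% and ABHD11-201 43.6% against 0.0233%. In EIF4A3 knockdown BLCAP-201 held 81.6% against 16.4%, ASB6-201 76.4%, MINK1-202 63.9%, MRC2-201 56.3%, and SGMS1-201 44.1% against 0.195%. At day 10 TOMM40L-202 held 74.9% against 7.56%, MINK1-202 72.0% against 1.06%, SH3PXD2A-203 82.6% against 39.9%, GAS7-202 53.2% against 0.00108% and SUMO3-201 98.1% against 46.5%. The share of counts on retained-intron transcripts was 2.95% in undifferentiated cells, 3.24% at day 10, 2.75% with scramble, 2.73% and 2.26% with U2AF1 A and B, 2.42% with the NCBP1 hairpin and 2.40% with the EIF4A3 hairpin. Among 1676 genes with such a transcript, its share was more than 5 points higher in 37 and lower in 80 in U2AF1 knockdown. The numbers were 73 and 45 for set A, 26 and 160 for set B, 24 and 145 for NCBP1 and 17 and 149 for EIF4A3 knockdown, but also 14 and 152 for scramble against undifferentiated cells, and 137 and 126 at day 10.

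Small RNA of the sorted layers, for which another cell line is not excluded, was compared with undifferentiated cells. In all 3 layers the imprinted cluster on chromosome 14 was higher and the primate cluster on chromosome 19 was lower. MIR127 (ENSG00000207608, chr14:101349316-101349412) of the first cluster stood at 24.5 counts in undifferentiated cells, 10782 in ectoderm, 10384 in mesoderm and 75408 in endoderm. The cluster had 26 higher and 0 lower of 26, median log2 6.22 in ectoderm, 27 higher and 0 lower of 27, median log2 6.86 in mesoderm and 34 higher and 0 lower of 34, median log2 8.9998 in endoderm. The chromosome 19 cluster had 0 higher and 23 lower of 23 in each layer, median log2 -4.98, -3.23 and -4.38 in the same order. MIR516B2 was at 37.3 against 4352 in ectoderm (log2 -6.83). With members at 0 set to their bound, the chromosome 14 medians were 6.19 in ectoderm and 8.75 in endoderm. All 6 medians lay outside the middle 95% of matched random lists.

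Other miRNAs differed between the layers in size or direction. Mesoderm held MIR196B (970.5 against 0.292, log2 9.55) and MIR10B (52962 counts, with 304 in undifferentiated cells, 1416 in ectoderm and 3139 in endoderm), which lie in HOX clusters, and its mesoderm, muscle and vessel list had 7 higher and 0 lower of 7, median log2 3.68. The miR-371-373 cluster had 3 higher and 0 lower of 3, median log2 5.89 in endoderm, 3 higher and 0 lower of 3, median log2 2.81 in mesoderm and 0 higher and 3 lower of 3, median log2 -1.31 in ectoderm. Endoderm held the miR-200 family (5 higher and 0 lower of 5, median log2 4.76), MIR1263 (3255 against 0.585, log2 11.005) and MIR489 (29445 against 162, with 1589.8 in mesoderm). In ectoderm miR-17-92 and its paralogues had 4 higher and 0 lower of 7, median log2 1.17, with MIR20B (31564 against 4642) and MIR106A (16610.5 against 2455). Ectoderm also held MIR219-1 (5632 against 111), MIR1262 (1249.7 against 4.57) and MIR217 (103 against 1.85), with 603, 524 and 30.7 in mesoderm. In ectoderm MIR375 was at 31782 against 2088, with 96922 in mesoderm and too many fragments to estimate in endoderm. The endoderm and liver list had 4 higher and 0 lower of 7, median log2 3.85 in ectoderm. That list had 3 higher and 0 lower of 5, median log2 3.28 in mesoderm. Of these medians, those of the miR-371-373 cluster in ectoderm and mesoderm lay inside the middle 95%. The other genes named by rank were members of the chromosome 14 cluster that were higher (MIR369, MIR381, MIR411, MIR431, MIR485 and MIR493), members of the chromosome 19 cluster that were lower (MIR518E, MIR520D, MIR520G, MIR522, MIR526B and MIR1323), MIR1910 (6.55 against 471) in ectoderm and MIR183 (7011 against 128030) in mesoderm.

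Let-7 had 0 higher and 4 lower of 6, median log2 -1.73 in ectoderm, with MIRLET7A3 (5.82 against 229), and 2 higher and 1 lower of 7, median log2 -0.13 in mesoderm, where MIRLET7C (786 against 7.20) was higher. The miR-302 cluster had 0 higher and 1 lower of 3, median log2 0.33 in ectoderm and 1 higher and 0 lower of 3, median log2 0.46 in mesoderm, without MIR302A, which had a value only in ectoderm (697799 counts, 14.7% of that column) and too many fragments for an estimate in the other columns. Neural miRNAs had 4 higher and 4 lower of 12, median log2 0.00 in ectoderm, mirtrons 0 higher and 3 lower of 3, median log2 -2.67 in mesoderm, and p53 and stress miRNAs 4 higher and 1 lower of 6, median log2 1.4997 in endoderm with MIR34C (10445 against 926). Only the mirtron and ectoderm let-7 medians of these lay outside the middle 95% of matched lists. The list of blood miRNAs was not scored, as too few members were measured.

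In ectoderm 167 of 250 features passed 2-fold (82 higher, 85 lower), in mesoderm 132 of 258 (77 and 55) and in endoderm 167 of 266 (96 and 71). Draws from the modelled variance gave 28.1, 30.2 and 36.8 on average. In endoderm, equal totals moved the median log2 ratio of all features by -0.87, and leaving out the 5 most abundant features by -1.19, which gave 65 higher and 112 lower, and 58 and 128. The latter gave 63 and 77 in mesoderm, and TMM scaling 58 and 92 in ectoderm. On recovered reads edgeR called 69, 51 and 56 features, of which 13, 0 and 0 were called whichever library was left out (20 to 48, 0 to 6 and 0 to 46 calls without 1 library). MIR495 of the chromosome 14 cluster had 41 and 28 reads in ectoderm against 0 and 0 (adjusted p 4.56e-07), which became at most 0.0465 with 1 library left out.

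The layers were compared in pairs to ask which miRNAs separate them. Between ectoderm and mesoderm, MIR670 (1617 against 63.2, log2 4.66), MIR129-2 (1155 against 67.7, log2 4.07), MIR488 (356 against 34.1), MIR219-1 (5632 against 603), MIR1251 (529 against 80.9) and MIR219A2HG (6042 against 962) were higher in ectoderm, and MIR196B (7.91 against 970.5, log2 -6.77), MIR10B (1416 against 52962), MIR371A (1614 against 53399), MIR196A2 (11.1 against 303), MIR372 (2054 against 36714) and MIR373 (4920.1 against 85587) lower. The same 6 were highest in ectoderm against endoderm, for instance MIR129-2 (1155 against 10.4, log2 6.67), where MIR371A (1614 against 362945, log2 -7.81), MIR653 (466 against 97741), MIR1263 (14.8 against 3255), MIR888 (6.13 against 1265), MIR373 (4920.1 against 722604) and MIR372 (2054 against 299309) were lowest. Mesoderm held more MIR483 (474 against 10.9, log2 5.32), MIR503 (419.5 against 39.9) and MIR30C2 (1641 against 193) than endoderm, with MIR196B, MIR10B and MIR196A2, and less MIR888 (7.35 against 1265, log2 -7.24), MIR1263 (20.7 against 3255), MIR892A (13.3 against 1326), MIR1179 (34.99 against 1406), MIR2113 (12.7 against 354) and MIR200B (2583 against 61032). The chromosome 14 cluster was lower in ectoderm (0 higher and 33 lower of 34, median log2 -2.87) and mesoderm (0 higher and 34 lower of 34, median log2 -2.52) than in endoderm. The miR-200 family was too (0 higher and 5 lower of 5 in both, median log2 -5.17 and -3.85).

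Ectoderm against mesoderm gave 114 of 239 features (43 higher, 71 lower). Ectoderm against endoderm gave 148 of 248 (51 and 97), or 91 and 65 with equal totals, which moved the median by 0.85. Mesoderm against endoderm gave 126 of 254 (49 and 77), or 93 and 52 with equal totals, which moved it by 0.83. With recovered reads edgeR called 0 features between ectoderm and mesoderm (40 at an unadjusted p under 0.05), 32 between ectoderm and endoderm and 14 between mesoderm and endoderm, of which 0, 7 and 0 were called whichever library was left out.

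**Figure D5:**
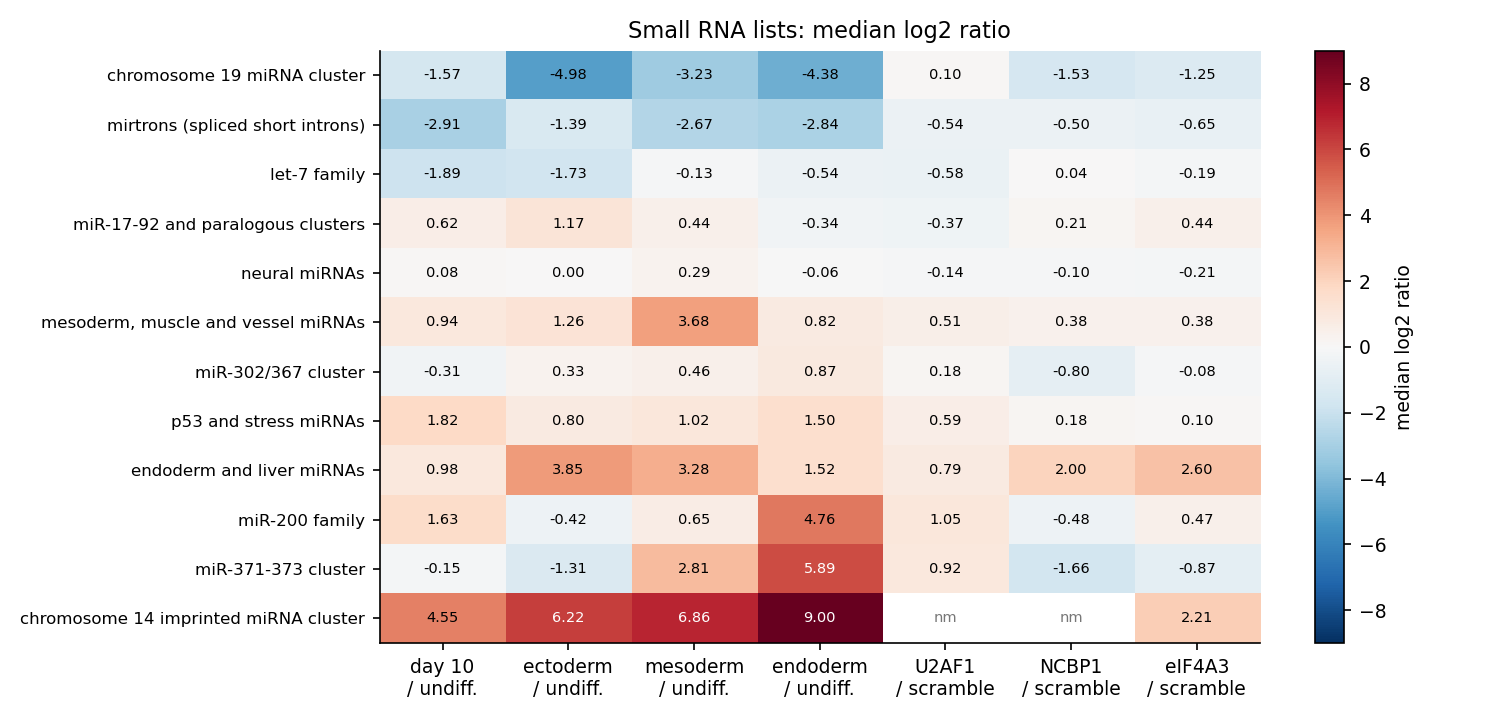
Median log2 ratio of the measured members of 12 small-RNA lists in 7 comparisons, coloured from lower (blue) to higher (red), where nm means too few members were measured. The chromosome 14 cluster reached 8.9998 in endoderm, and the chromosome 19 cluster stood at -4.98 in ectoderm, -1.53 with the NCBP1 hairpin and 0.10 with the U2AF1 sets.

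At day 10 the same clusters differed from undifferentiated cells. The chromosome 14 cluster had 9 higher and 0 lower of 9, median log2 4.55, with MIR127 (2078 against 24.5, log2 6.35), MIR411 (531 against 16.7), MIR654 (248 against 9.60) and MIR381 (253 against 12.2), and the chromosome 19 cluster 0 higher and 20 lower of 23, median log2 -1.57, with MIR516B2 (435 against 4352). MIR375 (ENSG00000198973, chr2:219866362-219866431), a miRNA of endocrine cells, was at 40946 against 2088 counts, and MIR1262 (435 against 4.57) was higher too. The let-7 family (0 higher and 5 lower of 6, median log2 -1.89) included MIRLET7A3 (12.8 against 229), and mirtrons (0 higher and 3 lower of 3, median log2 -2.91), which arise by splicing, included MIR1226 (5.72 against 72.2). p53 and stress miRNAs (4 higher and 1 lower of 6, median log2 1.82) included MIR34C (5783 against 926) and the hypoxia miRNA MIR210 (16186 against 2730.3). MIR504 (172 against 1750.4), MIR573 (34.4 against 334), MIR150 (38.5 against 282) and MIR1908 (44.5 against 318) were also among the lowest. In all 123 of 235 features passed 2-fold, 56 higher and 67 lower. Columns drawn from the modelled variance gave 22.4 on average. From recovered reads edgeR called 50 of 153 features, among them MIR493 (138 and 100 reads against 3 and 1, adjusted p 1.93e-08), and 7 of them whichever library was left out.

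All 3 knockdowns were compared with scramble for small RNA as well. MIR149 (ENSG00000207611, chr2:241395418-241395506) was lower in each, at 2297 counts with scramble, 100 and 149 with U2AF1 A and B, 164 with the NCBP1 hairpin and 51.2 with the EIF4A3 hairpin. MIR375 was higher in each, at 1868 with scramble and 5508, 6691, 7458 and 14511 in the same order. The chromosome 19 cluster was lower with the NCBP1 hairpin (0 higher and 21 lower of 22, median log2 -1.53) and the EIF4A3 hairpin (0 higher and 14 lower of 22, median log2 -1.25), and had 0 higher and 1 lower of 23, median log2 0.10 with the U2AF1 sets.

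U2AF1 knockdown had 3 higher and 0 lower of 5, median log2 1.05 in the miR-200 family and 1 higher and 0 lower of 3, median log2 0.92 in the miR-371-373 cluster, with MIR2113 (2302 against 122, log2 4.23), MIR141 (1476 against 502), MIR582 (281 against 95.8), MIR338 (1084 against 405) and MIR653 (745 against 278) higher and MIR1251 (67.2 against 319) and MIR181A1 (391 against 928) lower. Mirtrons had 0 higher and 0 lower of 3, median log2 -0.54, and let-7 0 higher and 0 lower of 6, median log2 -0.58. In NCBP1 knockdown the miR-371-373 cluster had 0 higher and 3 lower of 3, median log2 -1.66, and MIR200C (112 against 674), MIR141 (117 against 502), MIR520D (767 against 2973), MIR371A (1749 against 6574) and MIR526B (887 against 3189.9) were lower, while MIR181A1 (2359 against 928), MIR301B (10790.5 against 4694), MIR374A (4678 against 2045), MIR561 (2957 against 1341) and MIR340 (43360.1 against 20016) were higher. In EIF4A3 knockdown MIR127 (243 against 49.7), MIR196A2 (690.1 against 242), MIR367 (5387 against 1966), MIR592 (397 against 186) and MIR200A (326 against 159) were higher, and MIR573 (63.3 against 240.4), MIR516B2 (869.8 against 3241), MIR1323 (2937 against 10689.5), MIR520D (909 against 2973) and MIR522 (204 against 659) lower. The endoderm and liver list had 4 higher and 0 lower of 7 with the NCBP1 and the EIF4A3 hairpin, median log2 1.997 and 2.60.

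U2AF1 knockdown gave 21 of 218 small-RNA features past 2-fold (14 higher, 7 lower), NCBP1 knockdown 40 of 213 (13 and 27) and EIF4A3 knockdown 32 of 216 (9 and 23). Draws from the modelled variance gave 12.1, 18.3 and 19 on average. With equal totals, which moved the median by 0.14, EIF4A3 knockdown gave 18 and 19, and with equal totals without the top 5 NCBP1 knockdown gave 8 and 30. On recovered reads edgeR called 5 features in U2AF1 knockdown, 0 in NCBP1 knockdown (39 at an unadjusted p under 0.05) and 22 in EIF4A3 knockdown, none of them whichever library was left out. Between U2AF1 A and B 3 of 212 features passed 2-fold, among them MIR196A2 (149 against 954) and MIR320C1 (95.9 against 229.6). Between scramble and undifferentiated cells 2 of 212 did, MIR196A2 (242 against 5.97, log2 5.12) and MIR149 (2297 against 4777, log2 -1.06), and edgeR called 0 (7 at an unadjusted p under 0.05).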

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

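All tests of explanations in this part were chosen after the result they address was seen. Differences between the responses listed first were not tested, and no biological explanation was tested for them.

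Small RNAs were picked out where they passed 2-fold in opposite directions in a pair of germ layers against undifferentiated cells. Between ectoderm and mesoderm there were 5. MIR219A2HG was higher in ectoderm (6042 counts against 2370 in undifferentiated cells) and lower in mesoderm (962), and MIR371A, MIR372, MIR373 and MIR224 went the other way. Between ectoderm and endoderm there were 16. Among them MIR106A was at 16611 counts in ectoderm, 2455 in undifferentiated cells and 1158 in endoderm, and MIR200B at 806, 1642 and 61032. Between mesoderm and endoderm there were 3. Of these 5, 16 and 3, the same direction was kept by 5, 9 and 1 with equal totals by 3, 11 and 2 with TMM scaling, and by 3, 5 and 0 with equal totals without the 5 most abundant features, and MIR106A and MIR200B were kept by all.

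Genes of long RNA were picked out in the same way where the knockdowns passed 2-fold against scramble in opposite directions. Between U2AF1 and NCBP1 knockdown there were 8, namely CAV1, SPINK5, GDF3, ZNF676 and 1 unnamed gene, higher with U2AF1 hairpins, and PTPN5, FZD2 and PRKDC, lower with them. PRKDC was at 1704 counts with scramble, 2933 with U2AF1 A and 25.9 with U2AF1 B. Between U2AF1 and EIF4A3 knockdown there were 13, namely GDA, PRAC1, GDF3, PIWIL2 and 2 unnamed genes, higher with U2AF1 hairpins, and CDH6, GREB1L, ZEB1, PRTG, ZEB2, UNC5C and PRKDC, lower with them. With U2AF1 hairpins 6 of the 8 and 12 of the 13 were within 2-fold of undifferentiated cells, while scramble was at least 2-fold from these in 6 and 11. ZEB1 was at 51.4 counts in undifferentiated cells, 257 with scramble, and 59.5 and 42.7 with U2AF1 A and B, and PRTG at 891, 2791, 745 and 722.

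Most genes past 2-fold in NCBP1 and EIF4A3 knockdown were higher than with scramble. Scaling of whole columns is argued against unless most transcripts fell. For at most 60% to be higher, every ratio would have to be 0.20 log2 lower in NCBP1 and 0.18 in EIF4A3 knockdown. The other scalings raised them by 0.028 to 0.071. In NCBP1 knockdown a shift in scramble alone is argued against, as 96.0% of 376 genes (361) were also at least 2-fold above undifferentiated cells. That was not tested for EIF4A3. GC content of the transcripts could account for much of the pattern. After subtraction of the GC-bin median only 16.1% of 385 genes (62) stayed past 2-fold in NCBP1 and 29.7% of 300 (89) in EIF4A3 knockdown. The median log2 ratio of the higher genes went from 1.18 (SD 0.25) to 0.53 (SD 0.34) and from 1.19 (SD 0.38) to 0.70 (SD 0.51), so the calls ended because most ratios moved below the threshold. A trend with GC content can come from library preparation or from the cells, and the design holds nothing that separates these.

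Some genes were on in both untransduced columns and near 0 in the 5 transduced columns, or the reverse. Of the 21 ways to pick 2 of the 7 columns, only 1, the real one, separated as many as 19 genes by 4-fold among 13853 features, and the highest other separated 8, but a chance split stays open, since the columns were picked after their genes were seen. A loss or gain of 1 genomic segment is argued against, since at most 4 of the 17 genes with a position lay on 1 chromosome and they were spread over 9. Another stock or clone of cells for the transduced columns may be the source, but it cannot be told apart from transduction, hairpin vector and doxycycline, since all 5 columns share these, and in small RNA 1 of 244 features separated the same columns. PEG3 was at 22.5 and 3395 counts in undifferentiated and day-10 cells and at 0.391 to 2.64 in transduced cells, and H19 at 1.72 and 31.6 against 156 to 243.

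Genes past 2-fold in U2AF1 knockdown were weighed in the same way. A scramble column unlike every other column is argued against as the whole cause, since 70.8% of the 561 genes stayed past 2-fold against the mean of the NCBP1 and EIF4A3 columns, but only 35.8% did so against undifferentiated cells, and whether the scramble, NCBP1 and EIF4A3 columns had moved together was not tested. GC content is argued against as the whole cause within each set, where the correction moved bins of genes by -0.28 to 0.07 in A and -0.16 to 0.43 in B and left 89.8% of 578 and 79.0% of 778 genes past 2-fold, while in the mean of A and B the opposite trends cancel and decide nothing. A response that grows as the U2AF1 transcript falls could not be settled, because 56.7% of the genes were farther from scramble in set B, the set with less U2AF1 transcript. A difference in cell stock, and other targets of the hairpins, stay open and untested.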

How the results depend on the processing

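The GC correction, the limit of 2 modelled SDs, edgeR on recovered reads with all or all but 1 of the libraries, the list percentiles after GC correction and the scalings of small RNAs that went opposite ways were chosen after the result was seen, and the other alternatives before the data were examined. No paired analysis was possible because neither the pooled values nor the reads recovered from them tell which library carries which replicate number, so no replicate block was fitted. On the recovered reads DESeq2, its size factors, the planned filters, 1 fit of all groups, sets A and B as 1 group of 4 libraries, a fit without the germ layers, camera and fry were left out, as were Simes or F tests on isoforms. Depth limits what was called, since 198 to 228 of 501 to 548 small-RNA features above 0, and 12222 to 12989 of 28456 to 30705 long-RNA features, reached 200 counts.

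With pseudocount 10, TMM or median-ratio scaling, all 23 counts of features past 2-fold stayed within 1.5 times of the main value, and with equal totals 22 did. None of 297 ratios named by rank reversed under another scaling, pseudocount or GC correction. But 46 moved by over the modelled SD with pseudocount 10 and 26 with equal totals. So did 26 of small RNA with equal totals without the top 5 (95 did not) and 10 with GC correction (166 did not). The middle 95% of matched lists excluded 222 of 545 list medians, and that of unmatched lists 192. Of 171 long-RNA list calls 148 stayed after GC correction, among them all at day 10 and for scramble. Under any scaling or GC correction 1 called list reversed, that for epithelial to mesenchymal transition in EIF4A3 knockdown, with a median of 0.20 that became -0.019 after GC correction, and the cause was not tested. The counts below moved by more than 1.5 times. For thresholds on fold or count the construction gives the cause, since a stricter limit passes fewer features, and elsewhere the cause was not tested.

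At 1.5-fold the features numbered 6487 at day 10, 1724 in U2AF1 knockdown, 1913 with set A, 2715 with set B, 2203 for A against B, 1730 in NCBP1 knockdown, 1596 in EIF4A3 knockdown, 1226 for scramble, 2878 for U2AF1 against NCBP1 knockdown, 2924 for U2AF1 against EIF4A3 knockdown and 223 for NCBP1 against EIF4A3 knockdown. For small RNA they numbered 61 in U2AF1 knockdown, 18 for A against B, 68 in NCBP1 knockdown, 75 in EIF4A3 knockdown and 16 for scramble. At 4-fold the features numbered 1038 at day 10, 89 in U2AF1 knockdown, 103 with set A, 118 with set B, 21 for A against B, 11 in NCBP1 knockdown, 16 in EIF4A3 knockdown, 42 for scramble, 125 for U2AF1 against NCBP1 knockdown, 126 for U2AF1 against EIF4A3 knockdown and 7 for NCBP1 against EIF4A3 knockdown. For small RNA there were 46 at day 10, 3 in U2AF1 knockdown, 1 for A against B, 3 in NCBP1 knockdown, 4 in EIF4A3 knockdown, 1 for scramble, 98 in ectoderm, 84 in mesoderm, 42 for ectoderm against mesoderm, 93 for ectoderm against endoderm and 78 for mesoderm against endoderm.

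With at least 50 counts in the higher group there were 1090 in U2AF1 knockdown, 1195 with set A, 1631 with set B, 1116 for A against B, 790 in NCBP1 knockdown, 636 in EIF4A3 knockdown, 734 for scramble, 1546 for U2AF1 against NCBP1 knockdown, 1515 for U2AF1 against EIF4A3 knockdown and 115 for NCBP1 against EIF4A3 knockdown. For small RNA that limit gave 6 for A against B, 63 in NCBP1 knockdown, 55 in EIF4A3 knockdown and 4 for scramble. With at least 1000 counts there were 1925 at day 10, 214 in U2AF1 knockdown, 252 with set A, 339 with set B, 201 for A against B, 157 in NCBP1 knockdown, 133 in EIF4A3 knockdown, 106 for scramble, 379 for U2AF1 against NCBP1 knockdown, 385 for U2AF1 against EIF4A3 knockdown and 6 for NCBP1 against EIF4A3 knockdown. For small RNA the higher limit gave 65 at day 10, 10 in U2AF1 knockdown, 1 for A against B, 21 in NCBP1 knockdown, 14 in EIF4A3 knockdown, 1 for scramble, 102 in ectoderm, 68 in mesoderm, 106 in endoderm, 60 for ectoderm against mesoderm, 93 for ectoderm against endoderm and 75 for mesoderm against endoderm.

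Calls by edgeR on recovered reads numbered 921 at day 10, 360 in U2AF1 knockdown, 259 with set A, 323 with set B, 89 for A against B, 34 in NCBP1 knockdown, 23 in EIF4A3 knockdown, 70 for scramble, 571 for U2AF1 against NCBP1 knockdown and 564 for U2AF1 against EIF4A3 knockdown, from features with low values only. Leaving out 1 library gave 432 to 1371 at day 10, 96 to 343 in U2AF1 knockdown, 3 to 154 in NCBP1 knockdown, 4 to 36 in EIF4A3 knockdown and 4 to 300 for scramble. For small RNA edgeR called 50 at day 10, 5 in U2AF1 knockdown, 0 in NCBP1 knockdown, 0 for scramble, 69 in ectoderm, 51 in mesoderm, 56 in endoderm, 0 for ectoderm against mesoderm, 32 for ectoderm against endoderm and 14 for mesoderm against endoderm, where the counts of 0 went with 39, 7 and 40 features at an unadjusted p under 0.05. Past 2-fold and 2 modelled SDs there were 21 for NCBP1 against EIF4A3 knockdown, and for small RNA 17 in NCBP1 knockdown, 13 in EIF4A3 knockdown and 1 for scramble. The ratio less the median of its GC bin left 239 for A against B, 78 in NCBP1 knockdown, 109 in EIF4A3 knockdown and 612 for U2AF1 against NCBP1 knockdown. For small RNA of scramble, equal totals left 1 feature, as did equal totals without the 5 most abundant features.

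Genes with moved isoform shares at a minimum of 100 counts numbered 522 at day 10, 159 in U2AF1 knockdown, 223 with set A, 320 with set B, 307 for A against B, 306 in NCBP1 knockdown, 265 in EIF4A3 knockdown, 205 for scramble, 230 for U2AF1 against NCBP1 knockdown, 240 for U2AF1 against EIF4A3 knockdown and 115 for NCBP1 against EIF4A3 knockdown. At a minimum of 2000 counts there were 107 at day 10, 22 in U2AF1 knockdown, 29 with set A, 67 with set B, 58 for A against B, 53 in NCBP1 knockdown, 28 in EIF4A3 knockdown, 17 for scramble, 39 for U2AF1 against NCBP1 knockdown, 39 for U2AF1 against EIF4A3 knockdown and 6 for NCBP1 against EIF4A3 knockdown. With the top 500 genes per direction, shared genes numbered 98 for U2AF1 with NCBP1, 120 for U2AF1 with EIF4A3 and 585 for NCBP1 with EIF4A3 knockdown, where 2-fold gave 15, 26 and 232.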

Other observations

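Single heat shock and interferon genes differed although the medians of their lists did not lie outside the middle 95% before GC correction. The heat shock genes HSPB1 (1077 against 368) and HSPA1A (1243 against 548) were higher in NCBP1 and EIF4A3 knockdown, where GC content moved with both. In the interferon list the NCBP1 column held more ISG15 (73.2 against 15.99), BST2 (724 against 270.3) and IRF7 (246 against 115), and the EIF4A3 column gave ISG15 (55.7 against 15.99).

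The p53 target BBC3 of the apoptosis list was above scramble (60.9 counts) with every hairpin. It was at 193 in U2AF1, 149.9 in NCBP1 and 209 in EIF4A3 knockdown, and only the last reached 200. The share of counts on transcripts annotated as subject to nonsense-mediated decay was 2.15% with scramble, 2.23% and 2.04% with U2AF1 A and B, 2.00% with the NCBP1 hairpin and 2.10% with the EIF4A3 hairpin.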
